A study of Mus musculus with 2 samples.

How the data were processed

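Single-cell RNA libraries were made from the thoracic oesophagus of Krt5-CreERT2:R26SmoM2/EYFP mice, in which tamoxifen switches on SmoM2, a constitutively active form of the Hedgehog signal transducer Smoothened, together with a yellow fluorescent reporter, in cells that express keratin 5. Per the labels, cells were taken 12 weeks after tamoxifen. Of the 2 libraries, 1 came from untreated mice and 1 from mice given ibuprofen at 0.6 g/l in the drinking water. Ibuprofen is a non-steroidal anti-inflammatory drug that inhibits the cyclooxygenases encoded by Ptgs1 and Ptgs2. The labels say both that all living cells were taken and that the sort was based on EpCam, an epithelial surface protein. A gate on EpCam-positive cells would remove most non-epithelial cells. The labels do not say which EpCam fractions were loaded, or how many mice entered each library.

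Per the labels' protocols, the libraries were made with the 10x Genomics Chromium Single Cell 3' v3 kit and sequenced on an Illumina NovaSeq instrument. In this assay each cell receives a barcode in a droplet, and each captured poly(A) RNA molecule receives a unique molecular identifier (UMI) near its 3' end. The submitters' processing notes name bcl2fastq, STAR, Cell Ranger 3.1.0 and the mm10 build. The gene annotation release, the settings for calling cells and any treatment of doublets are not given in the sources used here.

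The 4 files analysed were a list of cell barcodes and a list of genes for each library, both parts of a filtered gene-by-barcode matrix, per the file names. The barcode lists as deposited hold 1 sequence per line, and the gene lists hold an identifier, a symbol and a feature type. Neither kind of file holds a measurement. The UMI counts per gene and cell were not analysed here, so no depth per cell, cell type, cell share or expression level is reported. The planned clustering of cells, the shares of cell types and the expression comparison per cell type were not run. The rule for named genes that needs expression values was not applied, and the genes named below come from the gene lists fixed beforehand or, where stated, from symbols chosen after the gene list was seen.

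From these files the barcodes per library, the barcodes present in both and the pairs of barcodes that differ at exactly 1 base were counted with Python 3.11.15. Exact Poisson intervals for counts and exact (Clopper-Pearson) binomial intervals for shares, both at the 95% level, were computed with scipy 1.17.1. They cover counting error only. The number of shared barcodes was set against the number expected for 2 independent draws, which is the product of both barcode counts divided by the size of the pool of possible barcodes. The pool size is an assumption and does not come from the files: 6800000 was the main value and 3400000 the alternative. The formula was tested on simulated data with numpy 2.4.6. Over 100 pairs of draws of 20104 and 19925 barcodes, the mean number shared was 57.6 for the pool of 6800000, against 58.9 from the formula, and 118 for the pool of 3400000, against 118.

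Gene identifiers were matched to the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes. All coordinates are from that annotation, 1-based, since the gene lists carry none. Of the 32285 Ensembl identifiers in the list, 32235 (99.8%) were in that annotation and 50 were not. The listed symbol differed from the annotation's in 733 of the matched genes. An overlap between genes was counted where annotated exons, merged over transcripts, shared at least 1 base with exons of another listed gene. Before the data were examined, 22 gene lists were fixed: 6 lists of pathways or programmes and 16 of cell type markers, with 123 distinct symbols. Some items of these lists are not reported here by name. The alternatives tried were leaving out shared barcodes, matching barcodes within 1 base, the smaller pool and counting genes by symbol. With 1 library per group, no test between the treatments was possible and none was made.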

Results

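The series was designed to compare oesophageal cells of mice with activated Smoothened in keratin 5 cells, with and without ibuprofen in the drinking water. Each condition was represented by 1 library, so no value has a replicate check. The filtered matrix of the untreated library held 20104 cell barcodes (95% exact Poisson interval 19827 to 20384). The filtered matrix of the ibuprofen library held 19925 (19649 to 20204). Every barcode was 16 bases long, was distinct within its library and carried the suffix 1. UMI counts per gene were not analysed here. The lists show which genes and reporters the libraries could report and how many cell barcodes were called. They do not show which genes were higher or lower after ibuprofen, and doublets among the barcodes were not examined.

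The ibuprofen library held 179 fewer cell barcodes than the untreated library. The ratio of ibuprofen to untreated was 0.991 (95% exact binomial interval 0.972 to 1.01). The interval covers the counting of barcodes in these 2 libraries only and is not a test of the treatment. The number of called barcodes depends on how many cells were loaded and on how cells were called. It is not a measure of the cell content of the oesophagus.

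The libraries shared 105 barcode sequences (95% exact Poisson interval 85.9 to 127). These were 0.522% of the untreated barcodes (95% exact binomial interval 0.427% to 0.632%) and 0.527% of the ibuprofen barcodes (0.431% to 0.638%). Together the libraries held 39924 distinct sequences. The number expected for 2 independent draws was 58.9 with a pool of 6800000 possible barcodes, and the observed number was 1.78 times that (1.46 to 2.16). With a pool of 3400000, 118 were expected and the ratio was 0.891 (0.729 to 1.08), which includes 1. The excess over chance was therefore present only with the larger assumed pool of these 2. No pair of barcodes, within either library or between them, differed at exactly 1 base.

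Both libraries were counted against the same list of 32290 features, with the same entries in the same order. The list held 32285 Ensembl mouse genes and 5 added entries, named CRE, EGFP, mCherry, TdTomato and YFP. Of these, CRE shares its name with the recombinase of the Krt5-CreERT2 allele. YFP shares its name with the yellow fluorescent reporter carried by the SmoM2 allele. EGFP and YFP are closely related coding sequences, so reads from the reporter that fit both could not be assigned to either with certainty. There was no entry named EYFP and none named SmoM2. The Smo gene was listed once (ENSMUSG00000001761, GRCm38 chromosome 6, 29735503 to 29761365, plus strand). Since SmoM2 is a form of Smoothened, this entry may not separate SmoM2 transcripts from those of the endogenous gene.

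The Hedgehog list was complete, with all 10 genes present once and all annotated as protein-coding. It includes the receptor gene Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598, minus strand), which is also a transcriptional target of the pathway. It also includes the transcription factor Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974, minus strand), whose mRNA is widely read as a marker of pathway activity. Exons of Gli1 overlapped exons of Arhgap9 and Gm47200 on the opposite strand, and 3 of the 10 genes (Gli1, Gli3 and Shh) had such an overlap. The exons of Ptch1, Gli2, Hhip, Sufu, Ihh and Smo overlapped no other listed gene on either strand.

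All 13 genes of the prostaglandin list were present once. The drug's targets are Ptgs1, which encodes cyclooxygenase-1 (ENSMUSG00000047250, chromosome 2, 36230426 to 36252272, plus strand), and Ptgs2, which encodes cyclooxygenase-2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227, plus strand). Neither had an exon that overlapped another listed gene. The genes of the prostaglandin E receptors were all listed, and exons of Ptger2 and Ptger4 overlapped exons of Gm17173 and Ttc33, respectively, on the opposite strand. Ptgis, encoding prostacyclin synthase, and Tbxas1, encoding thromboxane synthase, also had an opposite-strand overlap. Opposite-strand overlaps bear on counts only if reads were counted without regard to strand. The strand setting is not given in the sources used here, and no effect on counts was examined.

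All 14 cytokine and chemokine genes were present once, and 3 had an opposite-strand overlap: Il1a with Gm14023, Il1b with Il1bos, and Cxcl10 with Art3. The genes of the neutrophil-attracting chemokines Cxcl1, Cxcl2, Cxcl3 and Cxcl5 lie on chromosome 5 between 90759360, the start of Cxcl5, and 90905938, the end of Cxcl2. None of them overlapped another listed gene. Several chemokine symbols outside the fixed lists, chosen after the gene list was seen, stood for more than 1 identifier: Ccl27a for 3, and Ccl19, Ccl21a, Ccl21b and Ccl21c for 2 each. In all, 38 symbols covered 78 identifiers, among them Ddit3, a stress-response transcription factor gene, with 2. None of the 122 listed genes of the fixed lists shared its symbol with another entry.

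The epithelial lists were also complete. The driver keratin gene Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898, minus strand) and the other 5 basal keratinocyte markers were each present once, without exon overlap. So were the 6 suprabasal markers, which include the differentiation keratin genes Krt4 and Krt13. All 8 genes of the columnar and embryonic-like programme were listed, with opposite-strand overlaps for Krt7 (Gm671) and Krt8 (Gm36026). The 6 markers of columnar-like epithelium share Krt7, Krt8, Krt18, Krt19 and Sox9 with that programme and add Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129, plus strand), the gene of the sort marker. The 4 proliferation genes (Mki67, Top2a, Ccnb1 and Cdk1) were listed and had no overlap. Of the 3 entries in the transgene and driver list, Krt5 and Smo were present and EYFP was not, under that name.

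Markers of the other cell types that the sort could hold were all listed once. These were 6 for fibroblasts, 4 each for smooth muscle, skeletal muscle, endothelium, and Schwann cells and glia, and 3 for erythrocytes. The immune lists held 5 for macrophages, 5 for neutrophils, 6 for dendritic cells, 6 for T cells, 5 for natural killer and innate lymphoid cells, 4 for B cells and 4 for mast cells. Gata3, a transcription factor gene of lymphoid cells that keratinocytes also express, was the only fixed gene with a same-strand overlap. It shared 1.94% of its exonic bases with 9230102O04Rik. Opposite-strand overlaps were present in 21 of the 122 listed genes. They included Csf1r, a macrophage growth factor receptor gene (with Hmgxb3), Tagln of smooth muscle (with Pcsk7 and Gm48529) and Cd3e of T cells (with Gm48719).

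By class, 21702 listed genes were annotated as protein-coding, which was 98.5% of the 22028 in the annotation. Long intergenic non-coding RNAs contributed 5605 of 5854 and antisense genes 2955 of 2959. Immunoglobulin segments and their pseudogenes gave 427 entries and T cell receptor segments and their pseudogenes gave 270. Chromosome M contributed 13 genes. None of the 2207 microRNA, 1507 small nucleolar RNA or 354 ribosomal RNA genes of the annotation was listed. The list held 1 of 9941 processed pseudogenes.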

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

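The alternatives reported in this part were chosen before the data were examined. The ratio of observed to expected shared barcodes was 1.78 with a pool of 6800000 and 0.891 with a pool of 3400000. Its construction shows the cause, since the expected number is inversely proportional to the assumed pool. Leaving out the barcodes present in both libraries gave 19999 untreated and 19820 ibuprofen barcodes, within 1.5 times the full counts. The shared barcodes were only 0.522% of the untreated and 0.527% of the ibuprofen barcodes, so this setting could not have moved the counts that far. Matching within 1 base left 105 shared barcodes, but no barcodes lay 1 base apart, so this setting tested nothing. Counting genes by symbol gave 32250 in place of 32290. With only 38 symbols repeated, that setting could not have moved the count far either. Alternatives on UMI minimum, mitochondrial share, cluster resolution, doublets, expression scale and minimum UMIs per gene had also been chosen and were not run, since UMI counts were not analysed here. Depth per cell is unknown, and nothing reported here bears on expression or cell type shares. No paired analysis was possible because each group has 1 library.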

Other observations

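The tests of base use and the reading of the smaller pool as a test of carry-over were chosen after the number of shared barcodes was seen, while the smaller pool itself was set beforehand. The libraries shared 105 barcodes, 1.78 times the number expected from a pool of 6800000 (95% interval 1.46 to 2.16). Uneven use of bases at single barcode positions was tested by a calculation from the base use of both libraries, with each position taken as independent. It raised the expected number by a factor of 1.03 over even use of all bases, below the lower bound of that interval. For a pool that uses the bases evenly at each position, this argues against uneven use of single bases as the whole cause. The base use of the pool is not given in the sources used here, so for other pools the factor cannot decide. Bases 8 and 9 were tied in both libraries, with 4 of the 16 possible pairs present, so they are not independent draws. Counting the tied bases once gave a factor of 1.03, but the near-even use of base 9 fixed that outcome, so it does not test the tie. Uneven use of pairs or longer stretches of bases stays open. A carry-over of barcodes between libraries, such as by index hopping, is a candidate explanation that stays open, as does a smaller pool. With 3400000 possible barcodes the ratio was 0.891 (0.729 to 1.08) and no excess remained to be explained, and the observed number would equal the expected one at a pool of 3810000 (3150000 to 4660000). What keeps it open is that the pool in use is not given in the sources used here, and that reads per barcode were not analysed. A further check, on barcodes complementary at adjacent bases, was also looked at and left out because its reading depends on the design of the barcode list. The design gives no biological explanation for shared barcodes, and none was tested.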
